A study of Arabidopsis thaliana with 18 samples.

How the data were processed

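Gene expression was measured in Arabidopsis thaliana cotyledons of 3 genotypes: the Col wild type (WT) and the T-DNA insertion mutants bes1-1 and bes1-3. BES1 is a transcription factor of brassinosteroid signalling. Cotyledons of 6-day-old plants were taken either before culture (0 h) or after 72 h of VISUAL, an in vitro culture in which leaf mesophyll is induced to form vascular cells. Per the labels' protocols, the induction medium held the auxin 2,4-D at 1.25 mg/L, the cytokinin kinetin at 0.25 mg/L and bikinin, an inhibitor of GSK3-like kinases, at 10 µM. The 18 samples, 1 biotin-labelled sample per array, form 6 groups of genotype and time with 3 arrays each, numbered replicates 1 to 3 in the labels. The labels do not say that replicates came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

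The authors deposited 1 value per probe set and array, used here as log2 signal. The log base was inferred from the values, which were never negative, with medians of 5.189 to 6.254 and highest values of 14 to 14.19 per array. The arrays were processed with Affymetrix Expression Console, per the submitters' processing notes. Its version, the background correction, the normalization and the summarisation are not given in the sources used here. The deposited values were not on a common scale: the 6 arrays of replicate 1 had medians of 5.189 to 5.464 and the 12 arrays of replicates 2 and 3 had medians of 5.913 to 6.254. The number of arrays limits the precision, and a shift of scale between arrays adds to the spread within every group.

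The table held 38408 probe sets. The platform table listed 17481 of them, 16722 with 1 gene and 759 with several; the other 20927 are unnamed here. Of the probe sets with 1 gene, 16574 were matched to a locus of the TAIR10.1 gene table, which was used for names only, with no coordinates, and gave 16411 distinct loci. The platform table named 85.8% of the protein-coding genes that have no symbol in the TAIR10.1 table and 16.8% of those that have one, so many well-studied genes were not analysed here. For 143 loci with several probe sets, the one with the highest mean over all arrays stood for the gene; 11 of these loci had probe sets called with opposite signs in the WT induction. Values of 7132 probe sets were identical on all arrays to those of another probe set. No column marked control probe sets, so none was left out. Probe sets with several genes or none entered the counts and were not named.

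The log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 6 group means over all 18 arrays and 12 residual degrees of freedom. Each of 11 contrasts was adjusted by the Benjamini-Hochberg method over all probe sets, and a probe set was called at an adjusted p below 0.05. For some contrasts the count at an unadjusted p under 0.05 is also given. Without any difference, calibrated p-values would place a share of 0.05 of the 38408 probe sets there. The counts of 364, 822, 975 and 1214 lie under that share and 1957 lies close to it. They are therefore no measure of probe sets close to a call, and the p-values of this fit may be too large. The contrasts were 72 h minus 0 h in each genotype (the induction), each mutant minus WT at each time, the difference in induction of each mutant (its induction minus that of WT) and bes1-1 minus bes1-3 at each time. Log2 fold changes are given with the standard error (SE) of the fit. A group mean below the mean lower quartile of that group's arrays was treated as not shown to be above background; among named genes called this held for the lower group of 23 of 100 in the WT induction, 19 of 91 in the bes1-1 induction and 17 of 93 in the bes1-3 induction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

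The groups, the tests, 18 gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 10 largest rises and 10 largest falls among called genes whose groups of arrays did not overlap (5 and 5 in the mutant inductions, at 0 h and between alleles; no condition on overlap in the differences in induction). It also named up to 4 called members of each list, or up to 2 uncalled members where none was called. The text takes them from the top of each ranking. Of 291 entries in the 18 lists, 37 were measured. For 5 lists no member was named by the platform table and these were not analysed here: the BES1 family, xylem regulators, epidermis, brassinosteroid synthesis and receptor, and senescence. The targeted gene BES1 could therefore not be used to check the labels. A further 19 lists were drawn up after the platform's gene names had been seen, but before any fold change had been seen. They were vascular development, secondary wall and lignin, expansins and xyloglucan endotransglucosylases (XTHs), plastid-encoded photosynthesis, plastid-encoded gene expression, nuclear photosynthesis, cell division and DNA replication, tubulins, and auxin metabolism and response. The others were SWEET sugar transporters, flavonoid synthesis, glutathione transferases, UDP-glycosyltransferases of families 73 to 76, defence peptides and immunity, cold and dehydration, autophagy, stomatal lineage regulators, leaf and lateral organ patterning, and defensin-like LCR peptides. Several genes stand in more than 1 list.

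Lists with at least 5 measured members were tested with limma's camera, which compares the members with all other genes, at a preset inter-gene correlation of 0.01. P-values were adjusted over the lists within a contrast, separately for the 2 such fixed lists and the 19 later ones. Of 22 tests of fixed lists, 9 were called; with a correlation estimated from the data, 0 were called by camera and the smallest adjusted p was 0.0617. Of 209 tests of the later lists, 69 were called by camera with the preset correlation, 0 with an estimated correlation (smallest adjusted p 0.272), and 28 by fry, which asks whether members move together without comparing them with other genes. Without a block, every camera call in the report is thus lost with an estimated correlation; with the replicate block and an estimated correlation, 0 of the 9 fixed and 8 of the 69 later list calls held.

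Replicate numbers came from the labels, and pairing was checked before calls were compared. Deviations from the group means were correlated across probe sets between samples of the same number. All correlations were over 0.1 in 8 contrasts, with lowest values of 0.168 to 0.271 in those contrasts. They were not in bes1-1 versus WT at 0 h (lowest 0.0106), the bes1-1 difference in induction (0.0106) or the bes1-3 difference in induction (0.0802). Where all correlations were over 0.1, the result is also given with the replicate number as a block (10 residual degrees of freedom). This was done where the block changed a call or moved a count by more than 1.5 times. Replicate 1 stood apart in every group, which can by itself correlate samples of the same number, and samples of different numbers were not compared. The check therefore cannot show that the numbers pair the samples. Because replicate 1 stood apart, replicate 1 against replicates 2 and 3 was treated as a batch. For each contrast the counts from replicates 2 and 3 alone are given; replicate 1 has 1 array per group and allows no test by itself, so its correlation with the mean of the others across probe sets is given.

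The fits were tested on simulated data. For bes1-1 versus WT at 72 h, the fit without a block recovered 6% of 100 probe sets changed by 1 on the log2 scale and 46% of those changed by 2, with 0 false calls of 38408 probe sets. With the replicate block it recovered 60% and 96%, with 10 false calls. For the bes1-1 difference in induction these shares were 0% and 10% without the block and 30% and 79% with it. The shares and false calls with the block apply to measured data only as far as samples of the same number share a shift. That was not shown, and for the bes1-1 difference in induction the lowest correlation between such samples was 0.0106. The simulation therefore does not give the recovery or false calls of the block in the measured data. In the simulation of bes1-1 versus WT at 72 h, camera gave a list of 25 genes shifted by -0.5 an adjusted p of 9.56e-21 and called 0 of 20 unshifted lists, over 16411 genes. The noise was drawn independently for every gene and the unshifted lists were random genes. This run does not show how often camera falsely calls lists of co-expressed genes.

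Alternatives were the replicate block, omission of the dimmest 25% of probe sets, quantile normalization, scaling to reference genes, a trended and robust prior (statmod 1.5.0), array weights, only the groups of the contrast in the fit, a 2-fold minimum, and omission of each array in turn. Omission of 1 array leaves replicate 1 unequally represented between the groups compared, so that its shift of scale enters the fold changes. A count or p-value that moves on omission may reflect this imbalance, which was not tested. For lists they were an estimated correlation, fry, the replicate block, all probe sets of the members and scaling to reference genes. Genes for the size of the induction were also chosen at 1 and 3 instead of 2 on the log2 scale. Chosen after seeing the data were the batch block, replicates 2 and 3 alone, named probe sets only and identical probe sets counted once. So were quantile normalization with the replicate block, the replicate block with an estimated correlation and the replicate block for the size of the induction. Omission of single mutant arrays for the agreement of the alleles was also chosen then. The 19 later lists were drawn up after the gene names, but before any fold change, had been seen. Scaling to reference genes moved the median log2 fold change of all probe sets by more than 0.1 in 2 contrasts, from -0.0339 to -0.177 in the WT induction and from 0.0329 to -0.188 in the bes1-3 induction; fold changes in the text are relative to the deposited scale.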

Results

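Log2 signals of 38408 probe sets were compared in cotyledons of WT, bes1-1 and bes1-3 Arabidopsis, taken at 0 h and after 72 h of VISUAL culture, with 3 arrays in each of the 6 groups. The first principal component held 53.7% of the variance and parted the 0 h arrays from the 72 h arrays. The second held 26.1% and parted the 6 arrays of replicate 1 from the other 12. The lower quartiles of the signal were 3.145 to 3.223 on the arrays of replicate 1 and 4.015 to 4.137 on the others. Each replicate number held 1 array of every group, so this difference was not confounded with genotype or time. Unless another n is given, each log2 fold change compares 3 arrays with 3 and stands with its SE.

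**Figure D1:**
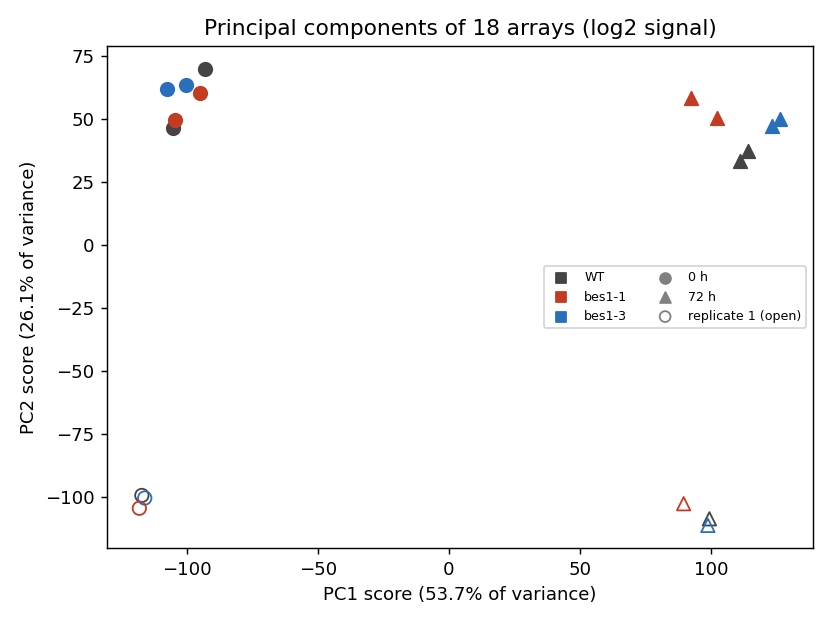
Positions of the 18 arrays on the first principal component (horizontal axis, 53.7% of the variance) and the second (vertical axis, 26.1%); grey is WT, red bes1-1 and blue bes1-3, circles are 0 h and triangles 72 h, and open symbols are replicate 1. The time points part along the horizontal axis and replicate 1 parts from the other replicates along the vertical axis.

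The genotypes carry insertions in BES1, whose transcript would be the first check of the labels. BES1 and its homologues were not analysed here, because the platform table names none of them.

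The WT induction shows which genes changed as cotyledons were cultured under vascular-inducing conditions. Several genes of vascular tissue rose. CLE44, which encodes a TDIF peptide that maintains procambial cells, rose by 4.22 ± 0.57 on the log2 scale, and CLE41, which encodes the same peptide, rose by 1.46 ± 0.38. All 5 measured procambium and cambium genes were called higher over all probe sets, and all 5 when adjusted over the list alone. IRX15, IRX15-L and GUT2 (IRX10), which act in the synthesis of xylan in secondary walls, rose by 5.0 ± 0.53, 4.49 ± 0.43 and 3.83 ± 0.43. The sieve element genes CLE45 and OPS rose by 3.2 and 3.12, while both measured genes of the companion cell list fell. SWEET11, which encodes a sucrose efflux transporter of phloem parenchyma rather than of companion cells, stood at -4.53, and AT3G12730 at -1.82. These were all 3 xylem wall genes and both genes of each phloem list, over all probe sets and adjusted over the list alone.

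Photosynthesis genes fell in the WT induction. Of 5 genes in the fixed list, 4 were called lower over all probe sets and 5 when adjusted over the list alone; PORB changed by -2.81, and PRK and SBPASE, enzymes of the Calvin cycle, by -2.79 and -2.74 ± 0.30. In the larger list of nuclear photosynthesis genes 27 of 32 fell, with a median of -1.96 (camera adjusted p = 1.32e-16, adjusted p = 0.598 with an estimated correlation), and NdhL, a subunit of the plastid NADH dehydrogenase-like complex, changed by -4.57 ± 0.59. Among plastid-encoded genes, 8 of 39 photosynthesis genes (camera adjusted p = 9.85e-05, adjusted p = 0.698 with an estimated correlation) and 11 of 14 gene expression genes (4.03e-07, adjusted p = 0.598 with an estimated correlation) were called lower. SPCH and MUTE, transcription factors that drive the stomatal lineage, changed by -3.26 and -2.80; these were 2 of the 3 stomatal lineage genes by either adjustment. The stomatal lineage regulators, a list that overlaps it, had 3 of 5 genes called lower (camera adjusted p = 0.00324, adjusted p = 0.598 with an estimated correlation).

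Genes of division, walls and hormone response also changed in the WT induction. The Aurora kinase genes AUR2, AUR1 and AUR3 rose by 3.13, 2.17 and 1.42, as 3 of 4 cell cycle genes over all probe sets and 4 when adjusted over the list alone. In the later list of cell division and DNA replication 11 of 26 genes were called higher and 0 lower (camera adjusted p = 1.56e-06, adjusted p = 0.698 with an estimated correlation). The secondary wall and lignin list had 9 of 23 genes higher and 1 lower, with AT5G66390, a class III peroxidase gene, at 6.31 ± 0.64 (camera adjusted p = 2.53e-04, adjusted p = 0.698 with an estimated correlation). Vascular development genes had 9 of 20 higher and 2 lower (0.0197), expansins and XTHs 9 of 27 higher and 2 lower (0.025) and tubulins 4 of 7 higher and 1 lower (0.025); each of these had an adjusted p = 0.698 with an estimated correlation, and expansins and XTHs were not called with the replicate block (0.129) or without WT replicate 1 at 72 h (0.0743). The expansin gene EXPA8, the only measured brassinosteroid-induced gene of the fixed lists, rose by 3.57 and was called by either adjustment. Of 4 auxin response genes, the auxin-conjugating enzyme genes GH3.1 and GH3.3 and the repressor gene IAA29 rose by 5.28, 2.96 and 4.41, and WES1, a further GH3 gene, changed by -1.20; all 4 were called by either adjustment. The cytokinin response regulator gene ARR15 rose by 3.95, as 1 of 2 cytokinin response genes over all probe sets and 2 adjusted over the list alone. The later auxin list had 8 of 25 genes higher and 2 lower, and its median of -0.211 had the opposite sign to its mean of 1.02 and its test (camera adjusted p = 0.0211, adjusted p = 0.698 with an estimated correlation, 0.129 with the replicate block).

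Autophagy genes rose in the WT induction, with 5 of 10 called higher and 0 lower; APG8A and ATG8H, which encode ATG8 proteins of the autophagosome, rose by 2.87 and 2.76 (camera adjusted p = 0.00104, adjusted p = 0.698 with an estimated correlation). Defence genes had 9 of 20 lower and 1 higher (9.5e-04, adjusted p = 0.598 with an estimated correlation); PDF1.2, a plant defensin gene and the only measured member of the fixed defence list, changed by -6.45 ± 0.86 and was called by either adjustment. For it and EXPA8 the p adjusted over the list alone is the unadjusted p. The root primordium genes LBD29 and LBD16 were not called by either adjustment, at -0.39 and -0.22. Of the 3 reference genes 0 were called by limma, and PEX4 stood at 0.42; the replicate block called 1. The lists of SWEET transporters (1 higher and 4 lower of 14; camera adjusted p = 0.0577), flavonoid synthesis (1 and 3 of 9; 0.377), glutathione transferases (4 and 2 of 15; 0.643) and UDP-glycosyltransferases (4 and 1 of 18; 0.643) were not called. Nor were cold and dehydration (3 and 1 of 13; 0.643), leaf and lateral organ patterning (1 and 1 of 14; 0.771) and LCR peptides (1 and 0 of 25; 0.952). In the flavonoid list DFR changed by -3.43, and the member CHI, which is AT2G43570, a chitinase gene, rose by 2.13.

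In the WT induction limma called 3342 probe sets higher and 4152 lower. The largest rises were those of AT2G31540 (8.18 ± 0.83; adjusted p = 2.93e-06), AT5G40020 (7.60 ± 0.37; 4.43e-09) and AT1G47271 (7.22 ± 0.43), and the largest falls those of AT3G20395 (-8.23 ± 0.38; 2.86e-09), AT3G55240 (-6.86) and ECS1 (-6.76). The lower of the 2 group means lay below the lower quartile of its arrays for 23 of 100 named genes called, among them AT2G31540, AT5G40020, AT3G20395, AT3G55240, IRX15, CLE45, ARR15, MUTE and PDF1.2, so the sizes of their changes are uncertain. Camera gave adjusted p-values of 1.7e-04 for procambium and 1.02e-04 for photosynthesis; each had an adjusted p = 0.0736 with an estimated correlation. With the replicate block 7268 were higher and 7982 lower, and within replicates 2 and 3 alone 5438 and 6446. Replicate 1 correlated with the mean of the others at r = 0.887 across probe sets, which are not independent replicates.

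Both mutants were induced as well, which asks whether the response needs BES1. CLE44 rose by 4.60 in bes1-1 and 4.00 in bes1-3, and OPS by 3.95 and 3.69. IRX15 rose by 2.24 in bes1-1 and 3.73 in bes1-3, IRX15-L by 2.71 and 3.37, GUT2 by 2.33 and 3.51, AT5G66390 by 3.45 and 4.17 and TBL33 by 3.36 and 4.70. All 5 procambium genes were called higher in each mutant (camera adjusted p = 4.38e-05 in bes1-1 and 2.32e-04 in bes1-3), as were all 3 xylem wall genes, and all 5 photosynthesis genes were called lower (4.38e-05 and 1.93e-05). For both lists the adjusted p = 0.0617 with an estimated correlation in bes1-1 and 0.0791 in bes1-3. In the nuclear photosynthesis list 28 of 32 genes fell in bes1-1 and 29 in bes1-3 (camera adjusted p = 1.12e-17 and 1.68e-19, adjusted p = 0.487 and 0.51 with an estimated correlation). In the cell division list 19 of 26 genes rose in each mutant (camera adjusted p = 1.4e-13 and 6.96e-13, adjusted p = 0.487 and 0.534 with an estimated correlation).

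The autophagy list had 1 gene higher and 1 lower of 10 in bes1-1 (camera adjusted p = 0.494), and 3 higher in bes1-3 (0.0281, adjusted p = 0.653 with an estimated correlation). Secondary wall genes had 8 of 23 higher and 2 lower in bes1-1 (0.0436, adjusted p = 0.859 with an estimated correlation, 0.0573 with the replicate block, 0.0705 without bes1-1 replicate 2 at 0 h and 0.0677 without bes1-1 replicate 3 at 72 h) and 11 higher and 2 lower in bes1-3 (0.00456, adjusted p = 0.653 with an estimated correlation). In bes1-1 the largest changes were those of LCR25 (7.78) and AT5G52390 (7.54), and of AT3G20395 (-6.90) and AT1G62510 (-6.69); in bes1-3 they were those of LCR25 (7.49) and AT1G47271 (7.43), and of AT3G20395 (-7.75) and AT2G36690 (-6.85). The lower of the 2 group means lay below the lower quartile of its arrays for 19 of 91 named genes called in bes1-1 and 17 of 93 in bes1-3. Among them were LCR25 and AT1G62510 in bes1-1, AT1G47271 in bes1-3 and IRX15 in both, so the sizes of these changes are uncertain.

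In bes1-1, limma called 4191 probe sets higher and 3748 lower over the induction, 10957 and 8415 with the replicate block, and 7568 and 6519 within replicates 2 and 3. In bes1-3 these counts were 3969 and 4389, 9307 and 8195, and 7179 and 6845; after scaling to reference genes 4644 were higher and 9137 lower. Replicate 1 correlated with the mean of the others at r = 0.86 in bes1-1 and 0.886 in bes1-3 across probe sets. An effect called in 1 genotype and not in another is not thereby shown to differ; the differences were tested separately.

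**Figure D2:**
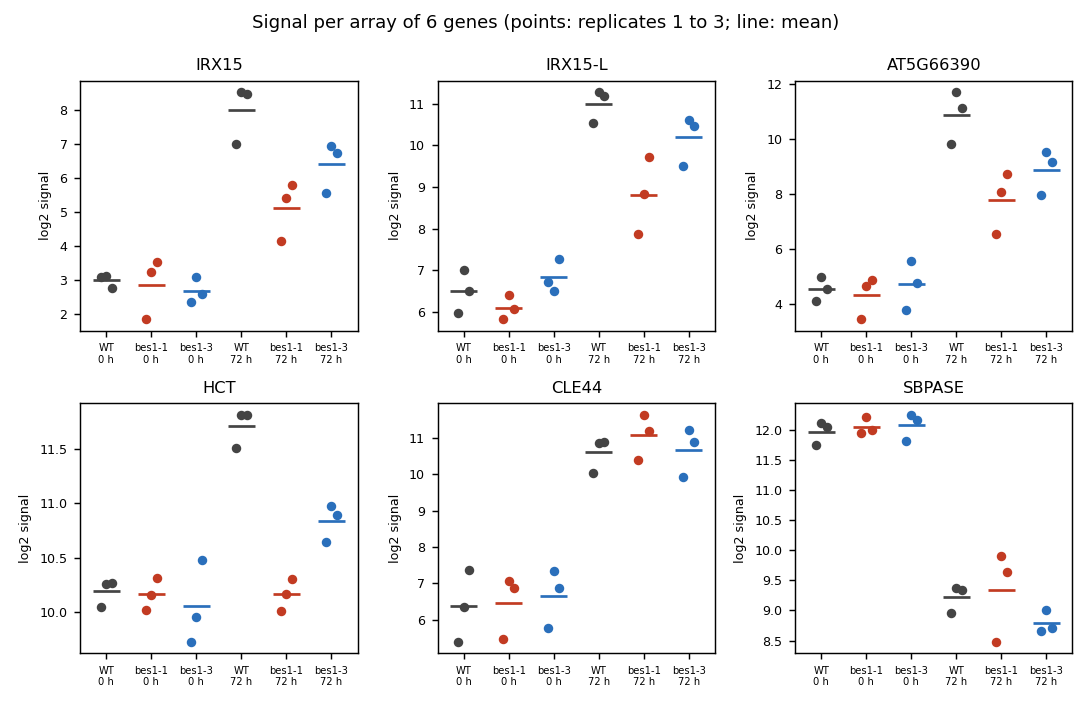
Log2 signal on each array (vertical axis) of IRX15, IRX15-L, AT5G66390, HCT, CLE44 and SBPASE in the 6 groups of genotype and time (horizontal axis), with a line at each group's mean of 3 arrays. At 72 h IRX15, IRX15-L, AT5G66390 and HCT were called lower in bes1-1 than in WT, and CLE44 and SBPASE were not called.

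Before induction few genes were called different between mutants and WT, which does not show that few differed. In the simulation at 72 h, the fit without a block recovered 6% of bes1-1 log2 changes of 1 and 46% of those of 2. In bes1-1 at 0 h the farnesoic acid methyltransferase gene FAMT fell by 4.19 ± 0.51 on the log2 scale (adjusted p = 0.00468), and JRG21 fell by 2.32 ± 0.32 (0.0163); these were the only named genes called, and the bes1-1 mean of JRG21 (3.1) lay below the lower quartile of those arrays (3.81). Within replicates 2 and 3 neither was called, at adjusted p-values of 0.271 and 0.305, and JRG21 was also not called after quantile normalization (0.106) or scaling to reference genes (0.0851). Over 19 alternatives the adjusted p of FAMT in bes1-1 versus WT at 0 h ranged from 5.35e-04 to 0.271, and that of JRG21 in bes1-1 versus WT at 0 h from 0.0111 to 0.617. The lowest value of FAMT came from the replicate block, and pairing was not shown for this contrast. The flavonoid list was lower in bes1-1, with a median of -0.513 and 0 members called (camera adjusted p = 4.06e-06, adjusted p = 0.417 with an estimated correlation). Its anthocyanin synthesis gene DFR stood at -2.77, not called. Defence genes had a median of -0.186 (7.14e-06, adjusted p = 0.417 with an estimated correlation), with list means of 0.00347, -0.437 and -1.06 in replicates 1, 2 and 3, and PDF1.2 stood at -2.54 ± 0.86, not called over all probe sets. It was called when adjusted over the list alone, but as the only measured member of the fixed list its p there is unadjusted. The value rests mostly on replicate 3, with replicate differences of -0.326, -2.09 and -5.2, and was -1.49 without bes1-1 replicate 3 for PDF1.2 in bes1-1 versus WT at 0 h. UDP-glycosyltransferases had a median of -0.05 (0.0304, adjusted p = 0.988 with an estimated correlation). They were not called without WT replicate 1 (0.111), WT replicate 3 (0.174) or bes1-1 replicate 3 (0.427).

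For bes1-1 at 0 h, limma called 2 probe sets higher and 6 lower, the batch block 9 and 46, and replicates 2 and 3 alone 2 and 9, of which 3 were among the 8; replicate 1 had r = 0.237 with the others across probe sets, and replicates 2 and 3 had r = -0.108 with each other. Omission of a single array left 4 without WT replicate 1, 5 without WT replicate 2, 3 without WT replicate 3 and 3 without bes1-1 replicate 2, and a fit of only these groups called 3. For bes1-3 at 0 h, limma called 3 probe sets higher and 0 lower. At an unadjusted p under 0.05 there were 364, fewer than a share of 0.05 of all probe sets. None of the 3 has a gene name here and no list was called. The replicate block called 5 higher and 1 lower, and replicates 2 and 3 alone or a fit of only these groups called 0; replicate 1 had r = 0.0549 with the others across probe sets, and replicates 2 and 3 had r = -0.104 with each other.

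At 72 h several genes of secondary walls were lower in bes1-1 than in WT. AT5G66390 fell by 3.1 ± 0.64 on the log2 scale (adjusted p = 0.035), IRX15 by 2.89 ± 0.53 (0.0177), IRX15-L by 2.19 ± 0.43 (0.0285) and HCT, an enzyme gene of lignin synthesis, by 1.55 ± 0.21 (0.00278). These 4 of 23 secondary wall genes were called over all probe sets, and 6 when adjusted over the list alone; the replicate block called 8 lower and 1 higher. The list median was -0.345 (camera adjusted p = 6.3e-06, adjusted p = 0.962 with an estimated correlation). Of the 3 fixed xylem wall genes 2 were lower over all probe sets and 3 when adjusted over the list alone, with GUT2 at -1.49 (adjusted p = 0.163, and 0.000286 with the replicate block).

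Other genes lower in bes1-1 at 72 h were AT5G23750, a remorin gene (-4.36 ± 0.47; adjusted p = 5.23e-04), AT3G49070 (-4.21), AT2G14095 (-4.02), AT1G05310 (-3.99 ± 0.45; 7.32e-04), AT2G18490 (-3.73), AT5G59845 (-3.63), AT4G34320 (-3.59) and AT5G40020 (-3.59). ALPHA-VPE, which encodes a vacuolar processing enzyme, changed by -3.58 ± 0.48, and the beta-glucosidase gene BGLU45 by -3.32. Genes higher in bes1-1 were AT3G22142 (3.86 ± 0.41; adjusted p = 4.48e-04), M10 (3.23 ± 0.68), AT1G09750 (3.15), AT5G13140 (3.12), AT4G31470 (3.09), AT3G54400 (3.04) and AT4G15160 (2.84 ± 0.26; 1.84e-04). From M10 to AT3G54400 in this order the differences were 1.18 to 1.91 in replicate 1 and 3.29 to 4.23 in replicates 2 and 3. Those of AT3G22142 and AT4G15160 were largest in replicate 1. The xyloglucan endotransglucosylase gene XTH20 rose by 2.42, from a WT mean of 2.95 that lay below the lower quartile of those arrays (3.73), so the size of its rise is uncertain.

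Autophagy genes had a median of -0.73 in bes1-1 at 72 h (camera adjusted p = 6.3e-06, adjusted p = 0.962 with an estimated correlation, and 0.0378 with the replicate block and an estimated correlation). None of the 10 was called over all probe sets and 7 were lower with the replicate block; ATG8H stood at -2.13 (adjusted p = 0.086, and 2.98e-05 with the block for ATG8H in bes1-1 versus WT at 72 h). Cell division genes had a median of 0.40 (6.3e-06, adjusted p = 0.962 with an estimated correlation), with 0 called by limma and 13 of 26 higher with the block. Glutathione transferases had a median of -0.27 (0.0034, adjusted p = 0.962 with an estimated correlation), with 0 called by limma and 7 of 15 lower with the block. Camera did not call photosynthesis (adjusted p = 0.994) or procambium genes (0.404).

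For bes1-1 at 72 h, limma called 94 probe sets higher and 230 lower, the replicate block 2743 and 2420, so that the higher share was 29% without the block and 53.1% with it. Replicates 2 and 3 alone gave 793 and 1225, with 310 of the 324 among them, and replicate 1 had r = 0.515 with the others across probe sets. The count was 204 without bes1-1 replicate 1, 159 without bes1-1 replicate 2, 56 without WT replicate 2 and 76 without WT replicate 3. A fit of only these groups called 2 probe sets higher and 0 lower, and IRX15, AT5G23750 and HCT then had adjusted p-values of 0.216, 0.1 and 0.156. These were the highest over 19 alternatives, and the lowest were 3.94e-06 for IRX15 in bes1-1 versus WT at 72 h, 5.54e-08 for AT5G23750 in bes1-1 versus WT at 72 h and 2.83e-06 for HCT in bes1-1 versus WT at 72 h.

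Several of the same genes differed in bes1-3 at 72 h. AT5G23750 fell by 3.28 ± 0.47 on the log2 scale (adjusted p = 0.0152), AT4G34320 by 3.08 ± 0.37 (0.00758), AT4G23110 by 2.81, AT1G05310 by 2.69, ALPHA-VPE by 2.66, AT2G34340 by 2.63, scpl28 by 2.51 and SFP2 by 2.42 ± 0.27 (0.00636). AT3G22142 rose by 2.90 ± 0.41 (0.0152), AT3G19200 by 2.29, XTH20 by 2.26 ± 0.33, AT2G27402 by 2.14, Prx37, a peroxidase gene, by 2.14, AT3G19430 by 1.91, bZIP70 by 1.77, AT3G18280 by 1.58 and AT4G15160 by 1.48. The WT means of AT3G19200 (2.75) and XTH20 (2.95) and the bes1-3 mean of AT4G23110 (3.33) lay below the lower quartile of those arrays. Within replicates 2 and 3 Prx37 was not called (adjusted p = 0.0703, with a range of 1.12e-04 to 0.306 over 19 alternatives for Prx37 in bes1-3 versus WT at 72 h), nor were AT2G27402, bZIP70 and AT4G15160. The wall genes AT5G66390 and IRX15 stood at -1.99 and -1.58, not called (adjusted p = 0.504 and 0.586), but called with the replicate block (0.00189 and 0.0142).

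Cell division genes were higher in bes1-3 at 72 h, with a median of 0.50 (camera adjusted p = 4.21e-12). The lists of secondary wall (-0.20; 0.0033), nuclear photosynthesis (-0.30; 9.31e-05), glutathione transferases (-0.35; 3.1e-04), UDP-glycosyltransferases (-0.17; 0.0325), autophagy (-0.55; 3.75e-04) and stomatal lineage regulators (-0.55; 0.00385) were lower. Each of these 7 lists had an adjusted p = 0.852 with an estimated correlation; with the block as well it was 0.0384 for cell division, glutathione transferases, autophagy and stomatal lineage regulators. The fixed photosynthesis list had a median of -0.43 (0.0272, adjusted p = 0.504 with an estimated correlation), not called without WT replicate 1 (0.123) or bes1-3 replicate 3 (0.0947). UDP-glycosyltransferases were not called without WT replicate 1 (0.188) or bes1-3 replicate 1 (0.0517). In these lists limma called 0 members, while the block called 17 of 26 cell division genes higher and 6 of 10 autophagy genes lower.

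For bes1-3 at 72 h, limma called 22 probe sets higher and 28 lower, and the replicate block 1480 and 1327; the higher share was 44% as deposited, 30.3% after quantile normalization (285 and 656) and 29.3% after scaling to reference genes (179 and 432). Replicates 2 and 3 alone gave 127 and 230, with 38 of the 50 among them, and replicate 1 had r = 0.384 with the others across probe sets. The count was 0 without bes1-3 replicate 1, 19 without bes1-3 replicate 2, 10 without bes1-3 replicate 3, 6 without WT replicate 2 and 0 without WT replicate 3, and a fit of only these groups called 0 (1957 at an unadjusted p under 0.05 in the fit of all groups). Each omission left replicate 1 unequally represented in the 2 groups, so the counts after omission also carry its shift of scale.

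The difference in induction asks whether genes responded otherwise in a mutant than in WT. In bes1-1 the change from 0 h to 72 h was lower than in WT for the remorin gene AT5G23750, by -4.60 on the log2 scale, and for AT1G05310 (-4.10), AT4G34320 (-3.78) and AT5G40020 (-3.50). Both 0 h means of AT5G40020 lay below the lower quartiles of their arrays. Its difference therefore mostly repeats that from WT at 72 h (-3.59), and its size is uncertain. The differences of Prx37 (3.6), AT3G22142 (3.54) and AT4G15160 (3.25, adjusted p = 0.00901) were positive. That of FAMT was 4.41, but its mean log2 signal fell in both genotypes, from 9.6 to 3.3 in WT and from 5.41 to 3.52 in bes1-1, so that the difference mostly repeats the lower level of bes1-1 at 0 h (-4.19). Both 72 h means lay below the lower quartiles of their arrays (3.73 and 3.8), where a further fall would not be seen, so the size of this difference is uncertain and a changed response is not shown. FAMT was not called within replicates 2 and 3 (adjusted p = 0.0766, with a range of 7.28e-04 to 0.137 over 25 alternatives for FAMT in bes1-1 difference in induction). The lowest value of this range came from the replicate block, for which pairing was not shown. Secondary wall (camera adjusted p = 3.7e-05), autophagy (3.7e-05) and glutathione transferase genes (0.00362) were lower as lists, and cell division (1.46e-05), defence (7.85e-05) and flavonoid genes (0.0337) were higher. All 6 lists had an adjusted p = 0.888 with an estimated correlation. The flavonoid list was not called without replicate 1 of WT at 0 h (0.305) or at 72 h (0.0848) or bes1-1 replicate 3 at 0 h (0.135). With the replicate block it was not called either. The defence list had means of 0.248, 0.635 and 1.66 in replicates 1, 2 and 3. The flavonoid and defence lists were lower in bes1-1 at 0 h and were not called at 72 h (medians 0.06 and 0.14, camera adjusted p = 0.777 and 0.106). PDF1.2 stood at -2.54 at 0 h and 0.41 at 72 h, where both means (1.79 and 1.38) lay below the lower quartiles. DFR stood at -2.77 and 1.51, with a difference of 4.28 (adjusted p = 0.0797). The chitinase gene CHI counts in the flavonoid list with a difference of 1.85. None of these was called, except the DFR difference with the replicate block (adjusted p = 0.00746), for which pairing was not shown. In bes1-3 cell division genes were higher (2.6e-13) and stomatal lineage regulators lower (0.00404), each with an adjusted p = 0.852 with an estimated correlation. Secondary wall (0.0217), nuclear photosynthesis (5.2e-04), flavonoid (0.0244) and glutathione transferase genes (3.46e-04) were lower, each with an adjusted p = 0.909 with an estimated correlation, as was the fixed photosynthesis list (0.0276, adjusted p = 0.506 with an estimated correlation). The secondary wall list was not called without WT replicate 1 at 72 h (0.061) or bes1-3 replicate 3 at 0 h (0.0726). With the replicate block it was not called either, nor was the flavonoid list. The flavonoid list was not called without WT replicate 2 or 3 at 0 h (0.311 and 0.0519) or WT replicate 3 at 72 h (0.0858). Its mean was 0.347 in replicate 1 against -0.852 and -0.648 in replicates 2 and 3. The fixed photosynthesis list was not called without bes1-3 replicate 1, WT replicate 2 or WT replicate 3 at 0 h (0.0527, 0.0553 and 0.0672), or without WT replicate 1 or bes1-3 replicate 3 at 72 h (0.11 and 0.0841).

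For the bes1-1 difference limma called 8 probe sets higher and 12 lower, the batch block 1638 and 1641, and replicates 2 and 3 alone 171 and 432, with 19 of the 20 among them; quantile normalization gave 220 and 994 and scaling to reference genes 174 and 595. At 0 h the count was 1, 13 and 1 without WT replicates 1, 2 and 3, and 7, 1 and 0 without bes1-1 replicates 1, 2 and 3. At 72 h it was 37, 1 and 1 without WT replicates 1, 2 and 3, and 39 and 8 without bes1-1 replicates 1 and 2; a fit of only these groups called 0. For the bes1-3 difference limma called 0 probe sets (975 at an unadjusted p under 0.05), the batch block 176 higher and 213 lower, and replicates 2 and 3 alone 1 and 23. Replicate 1 had r = 0.461 and 0.283 with the others across probe sets in bes1-1 and bes1-3.

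The alleles were compared for genes that differed from WT in both. At 72 h 42 probe sets were called in both, 16 higher and 26 lower, and 0 in opposite directions; AT5G23750, AT1G05310, AT4G34320, ALPHA-VPE, AT3G22142, XTH20 and AT4G15160 were among the genes called in both. Independent lists would share 0.0538 higher and 0.168 lower. With the replicate block 2026 were shared, 1045 higher and 981 lower, against 106 and 83.6 for independent lists, and replicates 2 and 3 alone shared 313. Both contrasts use the same 3 WT arrays, which cannot be divided, so part of the excess may come from the shared controls. In 20 simulations with shared controls and no effect the fold changes correlated at r = 0.501 and shared 0 calls; the measured r was 0.757 across probe sets, and the covariance 0.147 against 0.0322. Without any effect few probe sets would be called in either contrast. The 0 shared calls therefore do not show how far shared controls raise the count of 42. The count was 4 without WT replicate 2, 0 without WT replicate 3, and 0, 15 and 8 without bes1-3 replicates 1, 2 and 3. Without single bes1-1 arrays it was 28 to 39. At 0 h 1 probe set was shared (0.000156 higher and 0 lower for independent lists), 2 with the block, and 0 without WT replicate 1 or 2 or bes1-3 replicate 2 or 3; r was 0.273 against a simulated 0.5.

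**Figure D3:**
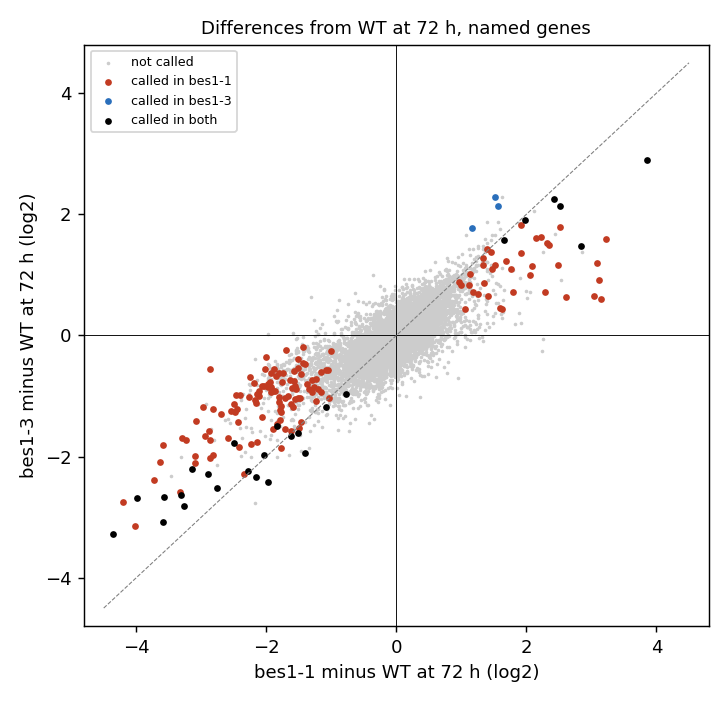
Log2 fold change of the named genes at 72 h in bes1-1 minus WT (horizontal axis) and in bes1-3 minus WT (vertical axis), each from 3 arrays against 3; grey genes were not called, red were called in bes1-1, blue in bes1-3 and black in both, and the dashed line marks equal values. Among probe sets called in both alleles 0 differed from WT in opposite directions, and both axes use the same WT arrays.

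The alleles were also compared directly. At 0 h FAMT was lower in bes1-1 than in bes1-3, by -4.20 ± 0.51 on the log2 scale (adjusted p = 0.00346), as were DFR (-3.36; 0.0433), AT1G73325 (-3.16), JRG21 (-2.84; 0.00217) and CCR2 (-2.62; 0.00944). Within replicates 2 and 3 none of these 5 genes was called (adjusted p = 0.179, 0.165, 0.131, 0.147 and 0.0876), and in a fit of only these groups none was called either. The flavonoid list was lower in bes1-1, with a median of -0.585 (camera adjusted p = 2.88e-08, adjusted p = 0.272 with an estimated correlation), as were defence genes (4.4e-05, adjusted p = 0.562 with an estimated correlation). The defence shift came mostly from replicate 3, with list means of 0.0513, -0.388 and -1.3 in replicates 1, 2 and 3. None of its members was called, and the list had an adjusted p = 0.016 without bes1-1 replicate 3. At 72 h limma called 0 named genes between the alleles without a block, and with the replicate block 35 higher and 207 lower in bes1-1. With the block IRX15-L (-1.39, adjusted p = 0.0462), TBL34 (-1.33, 0.0148), APG8A (-0.90, 0.0444) and ATG8H (-0.995, 0.0289) were lower and UGT76E11 (0.90, 0.0189) was higher. Nuclear photosynthesis genes had a median of 0.46 (2.37e-10), secondary wall genes -0.26 (1.15e-04), flavonoid genes 0.34 (0.0304, or 0.185 with the replicate block) and autophagy genes -0.19 (0.0109), each with an adjusted p = 0.944 with an estimated correlation; the fixed photosynthesis list had 0.55 (0.00138, adjusted p = 0.247 with an estimated correlation). In replicates 1, 2 and 3 the list means were -0.19, 0.94 and 0.582 for the fixed photosynthesis list and -0.088, 0.866 and 0.458 for nuclear photosynthesis. The fixed list was not called without bes1-1 replicate 2 (0.368). The flavonoid list was not called without bes1-1 replicate 1 or 3 (0.0509 and 0.0687) or bes1-3 replicate 2 or 3 (0.0807 and 0.0531). The autophagy list was not called without bes1-1 replicate 1 (0.1) or bes1-3 replicate 2 (0.0807).

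Between alleles at 0 h limma called 5 probe sets higher in bes1-1 and 22 lower, the replicate block 104 and 197, quantile normalization 18 and 36, replicates 2 and 3 alone 2 and 6, and a fit of only these groups 0 (1214 at an unadjusted p under 0.05 in the fit of all groups). The count was 7, 13 and 7 without bes1-3 replicates 1, 2 and 3, and 10 and 16 without bes1-1 replicates 2 and 3. At 72 h the counts were 2 and 2 in limma (822 at an unadjusted p under 0.05), 79 and 367 with the block, 4 and 29 after quantile normalization, 4 and 11 after scaling to reference genes, and 46 and 24 within replicates 2 and 3. At 72 h the count was 2 without bes1-3 replicate 1 or 3, 25 without bes1-1 replicate 1, and 2 in a fit of only these groups. Replicate 1 had r = 0.291 at 0 h and 0.229 at 72 h with the others across probe sets.

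The size of the induction was compared over genes chosen in the other mutant, so that the choice did not use the mutant measured. The choice was still not neutral, since the differences of the alleles from WT correlated at 72 h (r = 0.757 across probe sets). Genes chosen for a strong change in 1 allele may be those that change more in both mutants than in WT. The 1561 genes induced in bes1-3 had a median difference in induction of -0.185 in bes1-1 (SD 0.0667 over 3 replicates), with median inductions of 2.93 in WT and 2.66 in bes1-1, while the median over all probe sets was 0.0898. The 1447 genes induced in bes1-1 had 0.216 in bes1-3 (SD 0.124). Genes repressed in the other mutant had 0.224 in bes1-1 (SD 0.273, 1839 genes) and -0.172 in bes1-3 (SD 0.12, 1286 genes). The signs in bes1-3 are those that such a choice would favour, and the signs in bes1-1 are the opposite. All 3 replicates had the sign of the median for induced genes in both mutants and for repressed genes in bes1-3, and 2 of 3 for repressed genes in bes1-1. Without WT replicate 1 at 0 h the median for induced genes in bes1-1 was 0.066 and that for repressed genes in bes1-3 was 0.0145, both of the opposite sign. For induced genes in bes1-1 it was -0.317 and -0.318 without WT replicates 2 and 3 at 0 h, -0.395, -0.0924 and -0.068 without WT replicates 1, 2 and 3 at 72 h, and -0.00322 for genes chosen at 1 on the log2 scale. For induced genes in bes1-3 it was 0.455 and 0.0448 without WT replicates 1 and 3 at 0 h and 0.0178 without WT replicate 1 at 72 h, and for repressed genes in bes1-3 it was -0.371 without WT replicate 1 at 72 h.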

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

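Among the tests in this part, the comparison of covariance between replicates and the comparison of replicate 1 with the other replicates after quantile normalization were chosen only after the result was seen, as were the regroupings within batches. The added lists were drawn up after the platform's gene names were known, but before any fold change had been seen.

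The induction differed between bes1-1 and WT for 20 probe sets by a test of the difference itself in limma. On the log2 scale the difference was 4.41 for FAMT, which fell in both genotypes from a lower 0 h level in bes1-1 to 72 h means below the lower quartiles, so that its size is uncertain, 3.6 for Prx37, 3.54 for AT3G22142 and 3.25 for AT4G15160. It was -2.10 for AT5G49690, -2.34 for AT1G12450, -2.40 for AT5G45540, -2.77 for AT4G33150, -2.92 for AT5G07080 and -3.04 for AT1G17030. The lowest differences were -3.50 for AT5G40020, -3.78 for AT4G34320, -4.10 for AT1G05310 and -4.60 for AT5G23750. For AT5G40020 both 0 h means lay below the lower quartiles of their arrays, so that the size is uncertain. Chance was not excluded by the planned test: of 100 regroupings of genotype within each time, 7 called at least as many probe sets, the real one included, and the highest of the others called 72. Those regroupings can place the arrays of replicate 1 unevenly. Of all 72 regroupings that keep each array in its batch, 3 called at least as many (highest other 31), and with the batch block, which called 3279 probe sets, 2 did (highest other 5522). These shares are under 0.05, but they rest on the 60 regroupings that mixed the genotypes at 72 h. Mixing puts the difference between genotypes at 72 h into the spread, and those 60 called at most 1, and 5 with the batch block. Of the 11 others that left the genotypes at 72 h whole, 2 called as many, and 1 with the batch block. The test therefore does not exclude chance for a changed response, and does not separate one from a difference at 72 h. In a first version of this test only the groups compared were fitted, which gave a real count of 0 and a highest other count of 98; it was replaced because the reported counts come from the fit of all groups. For bes1-3 the real count was 0, all 100 regroupings called as many, and the highest other count was 7. Within batches all 72 called as many (highest other 6), and with the batch block, which called 389, 6 did (highest other 1049), so chance was not excluded.

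List medians that differed between the inductions of bes1-1 and WT by camera were -0.44 for secondary wall and lignin, -0.85 for autophagy, -0.565 for glutathione transferases, 0.485 for cell division, 0.623 for defence and 0.262 for flavonoid synthesis; the defence and flavonoid lists were lower in bes1-1 at 0 h and not called at 72 h. Between bes1-3 and WT they were -0.537 for photosynthesis, -0.327 for nuclear photosynthesis, -0.32 for secondary wall and lignin, -0.418 for flavonoid synthesis, -0.436 for glutathione transferases, -0.438 for stomatal lineage regulators and 0.588 for cell division. None of these 13 differences passed with an estimated correlation and no block.

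The other contrasts compare 3 arrays with 3, which make 10 splits, too few for a share under 0.05. In the inductions the real counts were 7494 in WT, 7939 in bes1-1 and 8358 in bes1-3, with a highest other count of 0 in each. Every other split mixed 0 h with 72 h arrays, which puts the induction into the spread. These counts of 0 therefore say nothing about chance. The real and highest other counts were 8 and 0 for bes1-1 and 3 and 7 for bes1-3 against WT at 0 h, and 324 and 0 for bes1-1 and 50 and 0 for bes1-3 at 72 h. Between the alleles they were 27 and 1 at 0 h and 4 and 0 at 72 h. As many probe sets as in the real split were called by 2 of the 10 splits for bes1-3 at 0 h and by 1, the real split itself, in each of the others. Among the 4 splits that part the replicate numbers as the real one does, the highest other count was 0 in the contrasts whose correlations were all over 0.1. With only the groups compared in the fit, the real count for bes1-3 against WT at 72 h was 0 and the highest other 24, so that all 10 splits called as many. In that fit the real counts were 6271, 5321 and 6724 for the WT, bes1-1 and bes1-3 inductions, 3 and 0 for bes1-1 and bes1-3 at 0 h, 2 for bes1-1 at 72 h, and 0 and 2 between the alleles at 0 h and 72 h, with a highest other count of 0 in each.

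More probe sets differed from WT in bes1-1 (324) than in bes1-3 (50) at 72 h. The gap depends on the processing, with 5163 against 2807 under the replicate block and 4898 against 4799, nearly equal, with array weights. The covariance of differences from WT between separate replicates was 1.83 times as large in bes1-1 as in bes1-3. It was larger in each of 3 replicate pairs (0.178 against 0.0786, 0.16 against 0.0983 and 0.203 against 0.118), which met the bound set against a chance size of the fold changes. The pairs come from only 3 replicates, both alleles use the same WT arrays, and no spread of the ratio was estimated. A chance size of the fold changes is therefore not excluded. Noisier bes1-1 arrays stay open: the ratio of the median residual SD was 1.14 (0.179 over 0.157), between the bounds of 1 and 1.2. A stronger effect of the bes1-1 allele also stays open: the direct contrast of the alleles at 72 h called 4 probe sets, and 446 with the replicate block, 79 higher and 367 lower in bes1-1.

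Of 23 secondary wall and lignin genes, 4 were called lower in bes1-1 than in WT at 72 h, 8 lower and 1 higher with the replicate block, and the camera call of the list was lost with an estimated correlation (adjusted p = 0.962). A generally smaller response to induction stays open: the median of the bes1-1 difference in induction over this list, -0.44, lay at percentile 0.52 of 10000 random lists matched on the bes1-3 induction, but at 0.02, 2.5 and 1.37 in the replicates, where a value under 2.5 was needed in each. Array scaling was not excluded by its bound, since the list median minus that of all named genes at 72 h was less than 2 SD below 0. It was -0.501 after quantile normalization (SD 0.356) and -0.438 as deposited (SD 0.3). In replicates 1, 2 and 3 it was -0.758, -0.392 and -0.164 as deposited and -0.893, -0.413 and -0.198 after quantile normalization. Scaling that this normalization removes would have made the shift smaller, so these values argue against such scaling. The loss of BES1, which the design gives as a biological explanation, was not tested further and may also account for the lower list.

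The arrays of replicate 1 stood apart from those of replicates 2 and 3. As deposited, their median distance from the mean of the others was 2.35 to 3.9 times that between replicates 2 and 3. After quantile normalization the ratio was 1.46 in the median over the 6 groups, with 1.07, 1.08, 1.42, 1.59, 1.51 and 1.82 in the groups. A difference in scale alone was not excluded by these bounds, because the ratio was neither at most 1.1 in the median nor over 1.3 in each group. Equal spread would give a ratio under 1, since the distance is taken from a mean of 2 arrays. All 6 ratios were above 1, which argues against a difference in scale alone. No biological explanation was tested, since the design gives none.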

How the results depend on the processing

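The batch block, replicates 2 and 3 alone, named probe sets only, identical probe sets counted once, quantile normalization with the replicate block, the replicate block with an estimated correlation, the replicate block for the size of the induction and omission of single mutant arrays for shared calls of the alleles were chosen only after the data were seen. Of 806 named gene results, 351 were called and 455 were not. None went from called to the opposite sign, or to a call of the opposite sign, under any alternative, while 133 uncalled ones changed sign uncalled. Of the 351 called, 90 were lost in a fit of only the groups of the contrast, 22 within replicates 2 and 3, 10 at 2-fold, 7 after scaling to reference genes, 3 after quantile normalization, 3 with a trended and robust prior and 2 with array weights, and single-array omissions lost a call 377 times. The replicate block lost 0 of these calls and added 86; array weights added 82, quantile normalization 48, scaling to reference genes 38 and replicates 2 and 3 alone 28. Signal over background limits genes near the lower quartiles of the arrays. The filter on probe set suffixes and the offset for linear values were not run, since the identifiers carry no suffix and the values are logarithmic. Where an omission leaves a group with 2 arrays, the spread is pooled over all groups. Such an omission also leaves replicate 1 unequally represented between the groups compared, so that its shift of scale enters the fold changes.

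The counts that follow moved by more than 1.5 times, in the order WT, bes1-1 and bes1-3 induction, bes1-1 and bes1-3 against WT at 0 h, the same at 72 h, bes1-1 and bes1-3 difference, and the alleles at 0 h and 72 h; the cause was not tested unless stated. With the replicate block they were 15250, 19372, 17502, 41, 6, 5163, 2807, 3199, 431, 301 and 446. With the batch block they were 15291, 19376, 17674, 55, 6, 5224, 2915, 3279, 389, 295 and 486. Quantile normalization gave 12352, 14700, 13812, 13, 6, 2530, 941, 1214, 60, 54 and 33, and with the replicate block 15041, 18260, 16767, 34, 7, 4657, 2510, 2971, 349, 288 and 262. Scaling to reference genes gave 12148, 13651 and 13781 for the inductions, 5 for bes1-3 at 0 h, 1987 and 611 at 72 h, 769 and 65 for the differences and 15 for the alleles at 72 h. Array weights gave 13379, 15162, 17332, 30 for bes1-1 at 0 h, 4898 and 4799 at 72 h, 1110 and 277 for the differences, and 123 and 911 for the alleles. Only the groups of the contrast in the fit gave 3 and 0 at 0 h, 2 and 0 at 72 h, 0 for the bes1-1 difference, and 0 and 2 for the alleles, with fewer samples to estimate the spread. Replicates 2 and 3 alone gave 11884, 14087 and 14024 for the inductions, 0 for bes1-3 at 0 h, 2018 and 357 at 72 h, 603 and 24 for the differences, and 8 and 70 for the alleles. With only named probe sets, where fewer were tested, the counts were 3535, 3470 and 3855, 2 and 0 at 0 h, 31 for the bes1-1 difference, and 12 and 0 for the alleles. The bes1-1 difference had 37 without the dimmest 25% of probe sets, 31 with a trended and robust prior and 37 with identical probe sets counted once.

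Of 9 fixed list calls, 0 held with an estimated correlation, with or without the replicate block. Of 69 calls of later lists, 0 held with an estimated correlation, 28 were called by fry, and 8 were called with the block and an estimated correlation. No list reversed. Of the 78 calls, the replicate block lost 15, replicates 2 and 3 alone 12 and scaling to reference genes 8; the block changed no other list call. In the order WT, bes1-1 and bes1-3, the block gave inductions of the auxin list an adjusted p of 0.129, 0.0956 and 0.18, and of expansins 0.129, 0.0975 and 0.17. It gave SWEET transporters 0.0603 in the bes1-1 and 0.0917 in the bes1-3 induction, flavonoid genes 0.0746 in the bes1-3 induction, 0.185 between alleles at 72 h, and 0.285 and 0.0574 in the bes1-1 and bes1-3 differences. It gave secondary wall genes 0.0573 in the bes1-1 induction and 0.0578 in the bes1-3 difference, and UDP-glycosyltransferases 0.114 in bes1-1 at 0 h. Shared calls of the alleles were 2 at 0 h and 2026 at 72 h with the block, and 0 and 313 within replicates 2 and 3. The median difference for induced genes in bes1-1 was -0.00322 for genes chosen at 1, -0.417 for genes chosen at 3 and -0.282 after quantile normalization.

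Omission of single arrays gave 6175 to 7047, 6170 to 7290 and 6705 to 7996 for the WT, bes1-1 and bes1-3 inductions, 3 to 11 and 2 to 3 for bes1-1 and bes1-3 at 0 h, and 56 to 383 and 0 to 65 at 72 h. It gave 0 to 39 for the bes1-1 difference, 0 to 0 for the bes1-3 difference, and 7 to 24 and 2 to 25 for the alleles at 0 h and 72 h. The lowest and highest were without WT replicates 2 and 1 for bes1-1 at 72 h, and without bes1-3 replicate 1 and WT replicate 1 for bes1-3 at 72 h. For the bes1-1 difference they were without bes1-1 replicate 3 at 0 h and bes1-1 replicate 1 at 72 h. Fixed list calls ranged from 7 to 9, later list calls from 67 to 73, and shared calls from 0 to 1 at 0 h and 0 to 62 at 72 h. The size of the induction ranged from -0.395 to 0.066 (induced, bes1-1), 0.0178 to 0.455 (induced, bes1-3), 0.0682 to 0.437 (repressed, bes1-1) and -0.371 to 0.0145 (repressed, bes1-3). The values of 0.066 and 0.0145 reversed the sign; both are without WT replicate 1 at 0 h, where the omission leaves replicate 1 unequally represented in the groups.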

Other observations

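No test was added for this part. The values come from lists added after the platform's gene names were seen and from the fixed naming rule.

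Single members of several lists changed in the WT induction, which shows nothing about their lists as groups. GSTF4 and GSTU25, glutathione transferase genes, rose by 5.21 and 4.93 on the log2 scale, although their list was not called. The defensin gene PDF2.1 rose by 5.70, while PDF1.2b changed by -5.31 and WRKY29, a transcription factor gene, by -3.65. The tubulin genes TUB7 and TUB5 moved apart, at 2.02 and -2.86. The expansin genes EXPB3, EXPA4 and EXPA15 rose by 4.61, 4.05 and 3.15, and WAG2 and IAA30 of the auxin list rose by 4.75 and 4.09. The lower group mean of GSTU25, PDF2.1, PDF1.2b, WAG2 and IAA30 lay below the lower quartile of its arrays, so the sizes of these changes are uncertain.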
